A study of Mus musculus with 9 samples.

How the data were processed

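The 9 paired-end RNA-seq libraries, with reads of 150 bases per the labels' protocols, were made from polyadenylated RNA of sorted lineage-negative, tdTomato-positive cells of mouse peri-implant fibrous tissue, 4 from Cre-only controls and 5 from Grem1 conditional knockouts. Groups and replicate numbers were read from the titles. The labels do not state that each library came from a different animal, so p-values measure the spread between these libraries.

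The authors deposited a matrix of normalized counts (a signal of gene counts divided by 1 size factor per library), with 27179 Entrez gene IDs in rows and 1 column per library. STAR, featureCounts and DESeq2 and the genome build mm39 are listed in the submitters' processing notes, with no versions; the annotation, the strand setting, the handling of reads that map to several places and any filter are not given in the sources used here. The authors also deposited a table of their own comparison, which per the file headers gives the mean normalized count (signal), the log2 fold change, its standard error, a test statistic (score) and p-values with adjusted p-values. The mean column equalled the row means of the matrix, and the score equalled the log2 fold change over its standard error. Values of that table are quoted only as the authors' own. All 9 columns of the matrix were used.

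Within each library every value was a whole multiple of the smallest value above 0 (tolerance 0.01 of a read), except 3 values of 1 gene. Dividing by that step recovered whole reads, 43.5 to 87.2 M per library, and at least 99.99% of the values above 0 in each library came out whole. These reads served for depth, counting intervals and the count tests tried as alternatives. Intervals and floors cover counting error only, since polymerase duplicates are not independent molecules; a group with no read was given a floor of 3 reads in each library, and groups with 1 to 3 reads an exact 95% Poisson interval. Gene symbols came from matching IDs to an NCBI gene table of assembly GRCm38.p6, used for names alone, and 25275 IDs matched. The 1904 IDs without a symbol held 0.45% to 0.988% of normalized counts and stayed in the tests. As that assembly differs from mm39, no coordinates are given. Reads of genes with near-identical copies, and of overlapping or antisense genes, cannot be assigned with certainty here.

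The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(normalized count + 1) with genotype as the only term, on genes with a normalized count of at least 10 in at least 4 libraries, which left 15832. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale and compare geometric means of the values plus 1. This understates the change of genes with low counts throughout a group, and can lie above or below the ratio of means where libraries of a group differ widely. The values were of the unit the design had assumed. Grem1 was also tested by an exact permutation test over all splits. Gene lists were tested with camera (preset correlation 0.01, at least 5 measured members, 37 lists, Benjamini-Hochberg over them), with an estimated correlation, and with fry. With the preset correlation 16 lists passed, with an estimated correlation 0 did, fry's directional test passed 4 (muscle, cartilage, oxidative phosphorylation and Schwann) and its mixed test 28. Members are counted past 0.05 over all genes and adjusted over the list alone; Grem1 was left out of every list. Means of cell type lists per library were compared by exact permutation tests.

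Before the data were examined, the tests, the lists and the rule for named genes were fixed. The rule took Grem1 and Lepr; in each direction the 10 largest changes past the test with a mean of at least 50 and 1 group lying wholly on one side of the other's mean, leaving out predicted genes and antigen receptor segments; in each list up to 4 passing members in each direction by p, or the 2 of smallest p where none passed; and the 3 most abundant passing genes in each direction. Further genes are named in the text where a count is small. Some genes the rule selects are not reported here and were not replaced; they stayed in every test and count. The lists of further muscle fibre genes, muscle stem cell genes, further Pi16-type fibroblast genes and Col15a1-type fibroblast genes were chosen after the main results were seen, as were 5 alternatives: the muscle list as a covariate, the depth class (over 60 M reads) as a covariate, only libraries under 60 M reads, leaving out control replicates 1 and 3 together, and thinning all libraries to the smallest read total.

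The other settings tried were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM and upper-quartile scaling, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, library quality weights, robust eBayes, a block for replicate number, the macrophage list or sex as a covariate, a fold threshold, and leaving out each library. The method was tested on simulated counts with the means of the controls and the dispersions and sizes of these libraries, for the comparison of Grem1 cKO with control (14947 genes, 200 of them changed). It recovered 18.9% of 95 genes changed 2-fold and 62.5% of 96 changed 4-fold that passed the filter, with 3 false calls, 3.7% of calls. The simulated genes were independent and held no difference that follows depth, so this share does not measure the false calls of the real comparison. A chi-square test of counts between all pairs of libraries gave at least 71 per degree of freedom, so no 2 libraries were near-duplicates. For gene copies, the longest transcript of each gene in the GENCODE mouse annotation for GRCm38 was broken into stretches of 100 bases and the percentage found in a transcript of another gene was computed with Python 3.11.15 and numpy 2.4.6; 95.2% of tested genes had a value. Figures were drawn with matplotlib 3.10.9.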

Results

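Gremlin 1 is a secreted antagonist of bone morphogenetic proteins (BMPs), and the study asked how the transcriptome of leptin receptor (LEPR) lineage stromal cells around a tibial implant differs when these cells lack the Grem1 gene. Polyadenylated RNA was sequenced from cells sorted from the fibrous tissue around the implant 2 weeks after surgery. The sorted cells were negative for blood lineage markers and carried the red fluorescent protein tdTomato, which marks cells in which a tamoxifen-inducible Cre recombinase driven by Lepr had been active. The labels name 4 libraries as Cre-only littermate controls and 5 as conditional knockouts (cKO), in which both Grem1 alleles were flanked by loxP sites. Control libraries held between 44.8 and 53.4 M (megareads) of recovered reads. Knockout replicates 1 to 4 held 76.3 to 87.2 M, and replicate 5 held 43.5 M. Depth therefore divided the libraries at 60 M reads into 4 knockouts on one side and 4 controls with 1 knockout on the other. The deeper side contained no control, so the only comparison at like depth set cKO replicate 5 against the 4 controls. In that comparison the spread comes from the controls alone and the lone knockout library is assumed to vary like them, so its values describe that library.

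Grem1 (Entrez 23892) was lower in every cKO library than in every control. Its normalized counts were 736, 517, 676 and 356 in control replicates 1 to 4, and 83.2, 46.4, 125, 133 and 60.8 in cKO replicates 1 to 5. The means were 572 ± 171 (SD, n = 4) and 89.6 ± 38.2 (SD, n = 5), a 6.57-fold lower level in the knockout on the log2(normalized count + 1) scale (log2 fold change -2.72, SE 0.43, limma adjusted p = 0.00781). An exact two-sided permutation test over all splits of the 9 libraries into 4 and 5 gave p = 0.00794, the smallest p these group sizes allow. The deleted part of the gene is not named in the labels, so reads from outside it may be included. At like depth, cKO replicate 5 differed from the 4 controls by -3.16, with a limma adjusted p of 0.153 from that single knockout library. Lepr (Entrez 16847), the gene driving Cre, did not pass the test (16409.7 ± 17808 in controls and 10782 ± 5696 in cKO libraries, log2 fold change 0.067, SE 1.07, limma adjusted p = 0.976) and ranged from 935 to 40594 in controls and from 1347 to 15785 in cKO libraries.

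**Figure D1:**
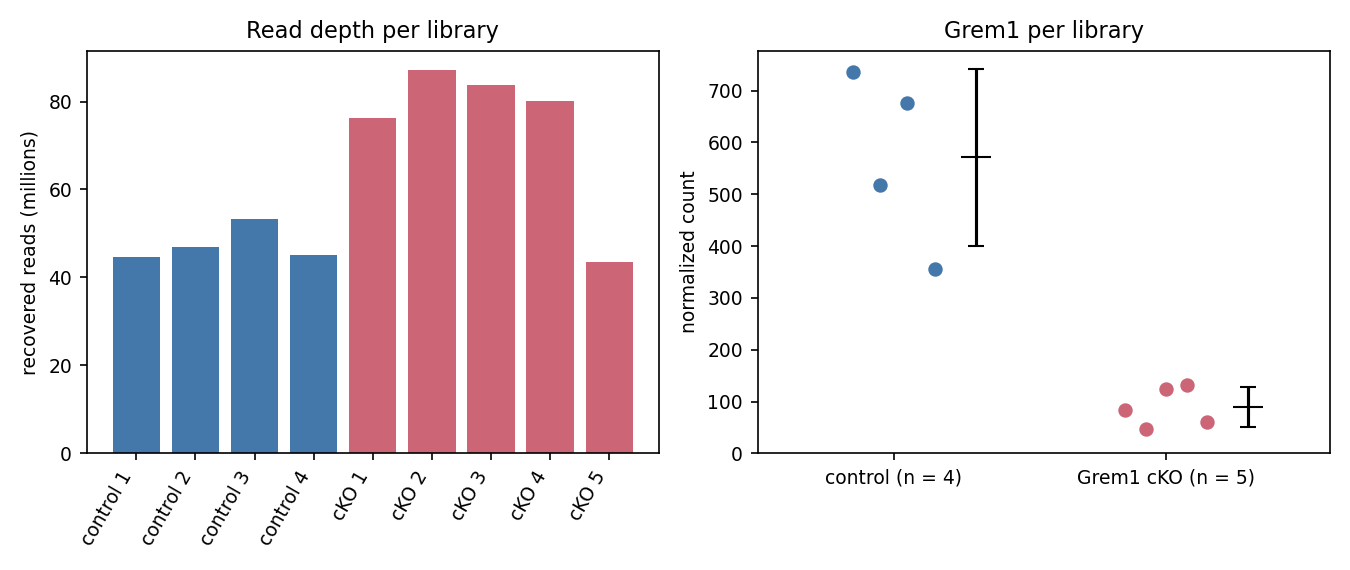
Left, recovered reads (M) for each library, with controls in blue and Grem1 cKO libraries in red. Right, Grem1 normalized count per library as points with the group mean and SD beside them (n = 4 and 5); the 5 cKO points lie between 46.4 and 133, all below the lowest control at 356.

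Across the 15832 genes tested, 730 were higher and 454 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05), 1184 in all. The groups did not overlap for 11.4% of all genes tested, where chance gives 1.59%, and for 994 of the 1184. Skeletal muscle genes rose most, with Mybpc2 (myosin-binding protein), Myot (myotilin), Myoz1 (myozenin), Myh4 and Myh2 (fast myosin heavy chains), Mb (myoglobin), Klhl31, Tnnc1 (troponin C), Cox6a2 and Cacna1s (muscle calcium channel) forming the 10 largest increases. The 10 largest decreases included Ms4a6d, Nos2 (inducible nitric oxide synthase), Gcnt4, Bcl6b, F8 (coagulation factor VIII), Ihh (Indian hedgehog), Itih5l-ps (a pseudogene), Gimap5 and Mrc1 (macrophage mannose receptor). Bcl6b, F8 and Gimap5 were high in control replicates 1 and 3 only. Bcl6b had 1604 and 2252 there, 44.1 and 92.2 in controls 2 and 4, and 105 in cKO replicate 1. For F8 these values were 830 and 734, 84.1 and 85.2, and 88.3. Gimap5 had 1521 and 1448 in controls 1 and 3, and 106 and 53.1 in controls 2 and 4. Nos2 had 709 ± 221 in controls, 426 in cKO replicate 5 and 0 in the other 4 knockouts. In the authors' deposited table Nos2, Gcnt4, Bcl6b and F8 were not called (adjusted p = 0.539, 0.0767, 0.159 and 0.228), and Itih5l-ps could not be matched to it. On the first principal component (37.9% of the variance) controls lay between -104 and -90.4, cKO replicates 1 to 4 at 74.1 or above, and cKO replicate 5 at -26.8. For 567 of the 1184 genes (47.9%) replicate 5 lay on the control side of the midpoint between the controls and the other 4 knockouts. Over all genes tested the share was 62.8%. These shares are not comparable, since calls made with replicate 5 included favour genes where it lies with the other knockouts. Between cKO replicate 5 and the controls alone, 83 genes passed, 46 of them among the 1184. Leaving out any 1 control, or any 1 of cKO replicates 1 to 4, brought the count to between 377 and 669, and leaving out cKO replicate 5 raised it to 3562. With edgeR's quasi-likelihood test on recovered reads 786 genes passed, and with DESeq2 2546.

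The most abundant genes that rose were Gsn (gelsolin, an actin-severing protein), Malat1 (a nuclear long noncoding RNA) and Serpinf1 (pigment epithelium-derived factor). Gsn had 121677 ± 27043 in controls and 1259232 ± 732359 in cKO libraries (8.96-fold, limma adjusted p = 0.0076), and cKO replicate 5 had 416142. Malat1 rose 2.84-fold and Serpinf1 2.11-fold, with limma adjusted p of 0.0187 and 0.0184. The most abundant genes that fell were the cartilage collagen genes Col2a1 and Col11a1 and the proteoglycan gene Bgn (biglycan).

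**Figure D2:**
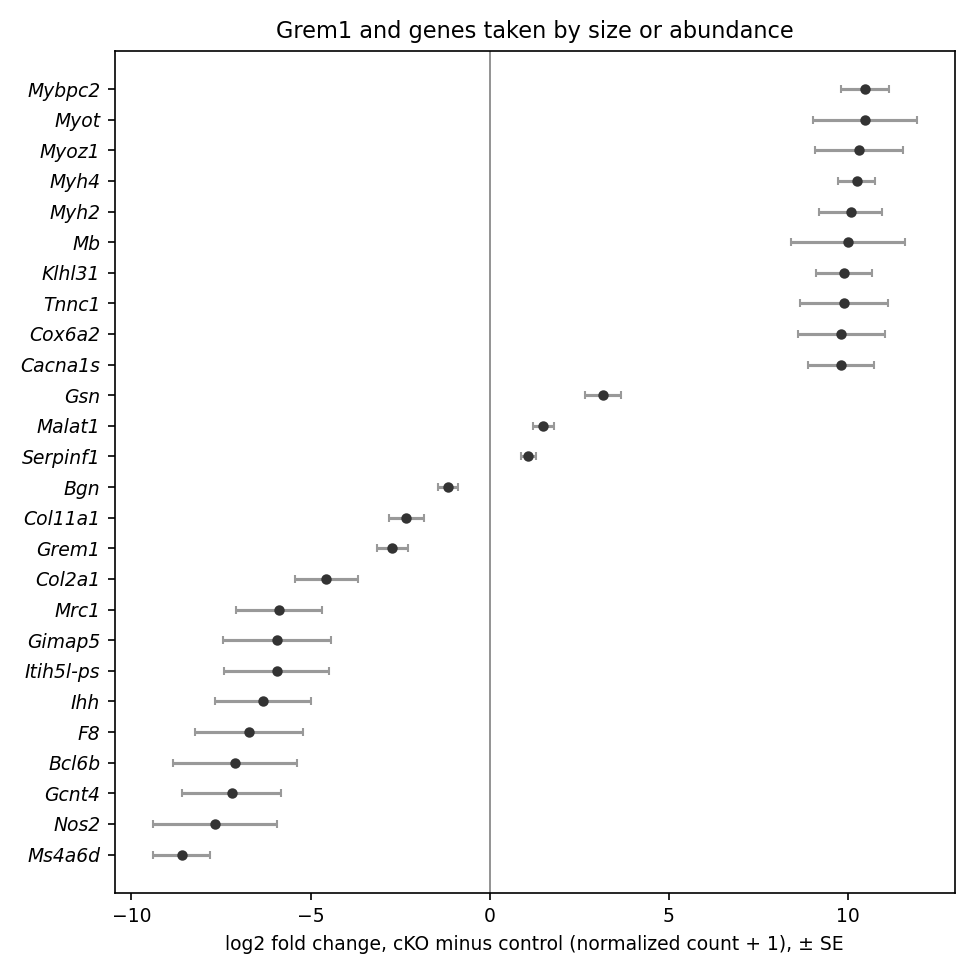
Log2 fold change of cKO over control, on log2(normalized count + 1), with its SE (limma, 9 libraries), for Grem1, the genes named from the 10 largest changes in each direction and the 3 most abundant changed genes in each direction. Grem1 lies at -2.72 and Gsn at 3.16; for genes with no or few reads in one group (Mybpc2, Klhl31, Cacna1s, Myh4, Myh2, Tnnc1, Ms4a6d and Mrc1) the position depends on the added count of 1 and is not a bound.

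All 17 measured members of the skeletal muscle list rose (median log2 fold change 7.79, and 17 when adjusted over the list alone). Acta1, the skeletal muscle actin, had 255 ± 151 in controls and 157077 ± 132556 in cKO libraries, and Tnnt3, the fast troponin T, had 117 ± 55.4 in controls and 22068 ± 17982 in cKO libraries. No read of Mybpc2, Klhl31 or Cacna1s occurred in any control, so that against a floor of 3 reads in each control library the knockout mean was at least 433-fold, 334-fold and 389.8-fold higher. Myh4 had 1 control read in all, a ratio of means of 4577 with a 95% counting interval of 822 to 180795. Myh2 had 3 and a ratio of 2191 (749.8 to 10625), and Tnnc1 had 2 and a ratio of 4229 (1171 to 34916). Those reads lay in control 2 for Myh4 and Myh2 and in control 4 for Tnnc1, and without that library the levels were at least 377-fold, 541-fold and 714-fold higher. Without cKO replicate 4 the bounds for Klhl31 and Cacna1s were 222-fold and 203-fold. The list made up 0.00602% to 0.0107% of normalized counts in controls and 0.192% to 1.5% in cKO libraries. Genes of Schwann cells, the glia of peripheral nerve, rose as well: 6 of 12 passed (9 when adjusted over the list alone; median 2.39), among them the myelin gene Prx (5.38-fold) and the glial regulator Sox10 (6.45-fold). In camera with its preset correlation of 0.01 both lists were higher (adjusted p = 5.1e-19 and 0.000153); with an estimated correlation the adjusted p was 0.301 and 0.634. Between cKO replicate 5 and the controls the medians were 7.02 and 1.38. With the skeletal muscle list as a covariate the Schwann median turned to -0.42 (camera adjusted p = 0.474), Sox10 to -0.18 and Prx to -2.44. That covariate nearly coincides with genotype, with list means of 3.24 to 6.47 in controls and 11.5 to 13.8 in cKO libraries. It leaves little of the genotype difference to estimate. A lost call or a changed sign with it, here and below, therefore does not show what muscle RNA accounts for.

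Cartilage genes were lower as a list. Of 20 members, 10 passed as lower and none as higher (median -4.13; 15 lower when adjusted over the list alone). Col2a1, the main collagen of hyaline cartilage, had 2554750 ± 950086 in controls and 215416 ± 313441 in cKO libraries (23.5-fold lower, 11.9-fold by the ratio of means, limma adjusted p = 0.0184). Ihh, a growth plate signal, fell 80.3-fold, Ucma (unique cartilage matrix-associated protein) 35.1-fold, and Hapln1, the link protein of aggrecan, 18-fold. By the ratio of means these were 32.9-fold, 15.2-fold and 8.25-fold. The knockout libraries were not alike: Col2a1 stood at 770230.1 in cKO replicate 5 and between 22618 and 133768 in the other 4. The list mean of cKO replicate 5 differed from the control mean by -0.98 log2 units and lay inside the range of the controls, against -4.11 for the other 4. Camera gave an adjusted p of 2.5e-08, and 0.634 as adjusted p with an estimated correlation; the median of cKO replicate 5 against controls was -1.08. With the skeletal muscle list as a covariate it was -2.18 (adjusted p = 0.195).

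The fibrosis and matrix list was lower in camera (adjusted p = 1.2e-06; adjusted p = 0.634 with an estimated correlation; median -1.28), with 2 of 28 members past the test over all genes and 16 when adjusted over the list alone. Those 2 were Thbs1 (thrombospondin 1, 3.04-fold lower) and Col12a1 (5.03-fold lower). In cKO replicate 5 against controls the median was 0.11, the other direction in that library, and with the skeletal muscle list as a covariate it was 0.36 (adjusted p = 0.358). Osteoblast genes did not move together (camera adjusted p = 0.811, direction lower while median 0.077 and mean 0.23 were above 0): Dkk1, a Wnt antagonist, rose 30.9-fold (14.1-fold by the ratio of means), and Omd (osteomodulin, 3.89-fold) and Col11a2 (4.06-fold) fell, out of 25. Adjusted over the list alone, 5 rose and 6 fell. In the tendon and fibrous tissue list 1 of 16 passed, Bgn (2.25-fold lower; 1 when adjusted over the list alone; camera adjusted p = 0.856). Of 10 osteocyte genes 2 rose, Dkk1 and Ackr3 (2.02-fold; 3 when adjusted over the list alone; camera adjusted p = 0.142, and 0.0348 without control 2).

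Genes of BMP signalling other than Grem1 were higher as lists. Camera adjusted p was 0.0156 for ligands, receptors and antagonists and 0.0156 for targets, and with an estimated correlation the adjusted p was 0.634 and 0.722. Among 32 BMP ligands, receptors and antagonists, 7 rose and 1 fell (14 and 2 when adjusted over the list alone; median 0.58). Bmp7 rose 4.95-fold, the BMP co-receptor gene Rgmb 3.07-fold and the activin and BMP antagonist Fst 3.01-fold, while the type I receptor gene Acvr1 fell 1.88-fold (limma adjusted p = 0.00359). Of 16 BMP target genes 1 passed, Hey1 (5.34-fold; 0 when adjusted over the list alone; list median 0.68). Without control 4 or cKO replicate 3 the target list lost its call (camera adjusted p = 0.0826 and 0.0568). With the macrophage list as a covariate both lists lost it (camera adjusted p = 0.284 and 0.197). That covariate also largely goes with genotype, with list means of 8.09 to 8.69 in controls and 9.19 in cKO replicate 2. In cKO replicates 1, 3, 4 and 5 they were 3.50 to 5.50. A lost call with it, here and below, therefore does not show what macrophage RNA accounts for. With the skeletal muscle list as a covariate the medians of the BMP lists were -0.26 and -0.32. In cKO replicate 5 against controls they were 0.064 and -0.23, and Hey1 stood at 553 there against a control mean of 519. Acvr1 in replicate 5 (1634) lay with the other knockouts.

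Stem and progenitor genes split into 2 directions, 4 of 19 higher and 3 lower (6 and 4 when adjusted over the list alone; camera adjusted p = 0.716). Pi16 and Dpp4, markers of a fibroblast population found in many tissues, rose 7.4-fold and 12.5-fold, Clec3b (tetranectin) 8.5-fold and Pdgfra 2.12-fold. Pi16 had 1446 ± 389 in controls and 10941 ± 4057 in cKO libraries (limma adjusted p = 0.00142), with 8620.3 in replicate 5. Mcam fell 3.05-fold, Cspg4 2.34-fold and Nt5e (CD73) 3.36-fold. Of 24 genes of the LEPR stromal niche, 3 rose, namely Ebf2 (3.09-fold), Serping1 (2.94-fold) and Pdgfra (3 when adjusted over the list alone; camera adjusted p = 0.631). Among 26 inflammatory genes the eosinophil chemokine Ccl11 rose 18-fold and the alarmin Il33 3.61-fold, and Il6 fell 6.83-fold (2 and 1 when adjusted over the list alone; camera adjusted p = 0.231). None of 16 adipocyte genes passed (camera adjusted p = 0.684; 0 when adjusted over the list alone), with the smallest p for Acaca (log2 fold change -0.79; 42.8% shared with another gene and therefore uncertain) and Slc2a4 (1.28).

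**Figure D3:**
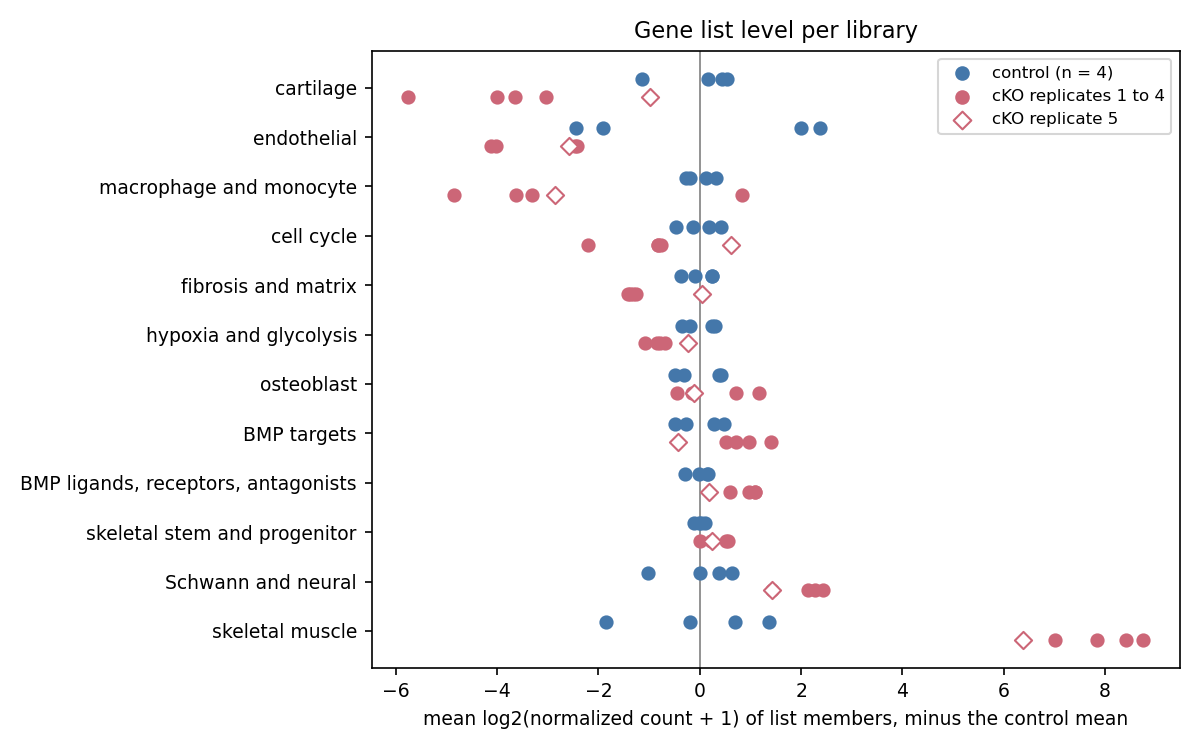
Mean log2(normalized count + 1) of the members of 12 gene lists in each library, minus the control mean, with controls as blue circles (n = 4), cKO replicates 1 to 4 as red circles and cKO replicate 5 as an open diamond. For cartilage the diamond lies at -0.98, among the controls, and for skeletal muscle at 6.38, near the other cKO libraries.

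Macrophage, endothelial, mast cell, megakaryocyte and erythroid genes were lower as lists. Of 17 macrophage and monocyte genes 1 passed, Mrc1, with 179.8 ± 197 in controls and 0.405 ± 0.603 in cKO libraries and a ratio of control to knockout means of 444 (95% counting interval 152 to 2154 from 3 knockout reads). This ratio rests on controls 1 and 3, with 270.2 and 416 against 16.6 and 16.8 in the other 2: it was 249.9 without control 3, 41.2 without both, and 1061 without cKO replicate 2. The list median was -3.03 (4 lower when adjusted over the list alone), yet cKO replicate 2, the knockout library with the highest Ptprc (CD45, 3674 normalized counts), lay above every control. Ms4a6d, of a gene family expressed in macrophages, had no read in any cKO library, against 499.7 ± 369.8 normalized counts in controls. Of 16 endothelial genes 2 fell, Flt1 (10.1-fold) and Cldn5 (13.6-fold, 23.2-fold by the ratio of means), and 13 when adjusted over the list alone (median -3.26). Endothelial list means were 13.4 and 13.8 in control replicates 1 and 3 and 8.95 and 9.48 in controls 2 and 4. Without controls 1 and 3 the median was -0.92 (camera adjusted p = 0.059). Flt1 and Cldn5 followed this split, with Flt1 at 7719 and 10035 in controls 1 and 3 and 632 and 1211 in controls 2 and 4. Controls 1 and 3 were also the only controls that expressed Xist. Among knockouts the library with Xist, replicate 2, had the lowest endothelial list mean, 7.28. Mast cell (1 of 6, Kit, 3.09-fold lower; 2 when adjusted over the list alone), megakaryocyte (0 of 9; 3) and erythroid lists (0 of 13; 0) were lower in camera as well, with the smallest p for Pf4 (log2 fold change -5.08) and Nrgn (-1.84), and for Tfrc (-1.26) and Hba-a2 (-3.57; 74.5% shared with another gene and therefore uncertain). Camera adjusted p was 0.000175, 5.3e-05, 0.0124, 0.00965 and 0.0274 for the macrophage, endothelial, mast cell, megakaryocyte and erythroid lists; with an estimated correlation the adjusted p was 0.634 for the first 4 and 0.774 for the erythroid list. In cKO replicate 5 against controls the medians were -1.85, -2.61, -0.051, 0.27 and 1.05. With the skeletal muscle list as a covariate they were -3.76, -3.93, 0.40, -0.26 and 0.39, and the endothelial list kept its call (adjusted p = 0.00827), while the other 4 had an adjusted p of 0.139 or more. The erythroid call was lost without control 4, cKO replicate 2 or cKO replicate 3 (camera adjusted p = 0.0985, 0.0556 and 0.22), and the mast cell call without controls 1 and 3 together (0.0867). With the macrophage list as a covariate the mast cell, megakaryocyte and erythroid lists lost their calls (camera adjusted p = 0.594, 0.095 and 0.332).

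Neutrophil, T and NK cell, and B and plasma cell lists did not pass camera (adjusted p = 0.263, 0.195 and 0.624), and none of their 15, 7 and 13 members passed over all genes or over the list alone. Their smallest p values belonged to Ltf (-1.42) and Ngp (-1.44), Trac (-1.66) and Lck (-1.98), and Blnk (2.43) and Jchain (-4.56), as log2 fold changes. Without cKO replicate 2 the neutrophil and the T and NK cell lists passed as lower (camera adjusted p = 0.000759 and 0.0128). The epithelial list was higher (1 of 7, Perp, 19.8-fold; 3 when adjusted over the list alone; camera adjusted p = 0.0364, and adjusted p = 0.634 with an estimated correlation), with a median of 0.012 in cKO replicate 5 against controls and -0.69 with the skeletal muscle list as a covariate. Its call was lost with the macrophage list as a covariate (camera adjusted p = 0.354) and without control 1, control 4, cKO replicate 1 or cKO replicate 3 (camera adjusted p = 0.0629, 0.0523, 0.0697 and 0.0568). In the osteoclast list (8 members, camera adjusted p = 0.716; median -0.29, mean 1.09) the calcitonin receptor gene Calcr, which had 327 in control 1 and at most 2.79 in the other controls, rose from 82.4 ± 163 to 2378 ± 1847 (adjusted p = 0.0615 in the authors' deposited table) and Nfatc1 fell 1.78-fold, both also over the list alone. In the smooth muscle and pericyte list (14 members, camera adjusted p = 0.104; direction lower, median -0.59; adjusted p = 0.0473 without control 3) 1 rose, Des (desmin, 6.82-fold), and 3 fell, among them Ndufa4l2 (2.14-fold; 1 and 5 when adjusted over the list alone). An exact two-sided permutation test of the list means found 0 of the cell type lists past Benjamini-Hochberg 0.05, where 5 had an unadjusted exact p under 0.05. The muscle and Schwann lists were higher in 5 of 5 cKO libraries than in every control (exact p = 0.00794 each, adjusted p = 0.0595).

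In camera with its preset correlation, glycolytic and hypoxia genes were lower as a list and genes of oxidative phosphorylation higher. Of 26 hypoxia and glycolysis genes 8 fell (16 lower and 2 higher when adjusted over the list alone; median -0.91), among them the phosphofructokinase gene Pfkl (3.39-fold), Pgam1 (4.26-fold), the enolase gene Eno1 (2.8-fold) and Pkm (1.95-fold). Pgam1 and Eno1 share 39.7% and 54.7% of their 100-base stretches with transcripts of other genes, so their counts are uncertain. Of 29 oxidative phosphorylation genes 6 rose (21 when adjusted over the list alone; median 0.43), such as Ndufb8 (1.63-fold), Ndufv1 (1.54-fold), Ndufa2 (1.49-fold) and Sdhc (1.43-fold). Camera adjusted p was 0.000265 and 6.3e-08, and with an estimated correlation the adjusted p was 0.634 for both; cKO replicate 5 against controls gave medians of -0.16 and 0.12. With the skeletal muscle list as a covariate they were -0.23 and -0.17 (adjusted p = 0.738 and 0.474). Cell cycle genes were lower as a list (camera adjusted p = 5.3e-05; adjusted p = 0.739 with an estimated correlation; median -0.72), with 0 of 38 members past the test over all genes or over the list alone. The smallest p values were for Kif20a (-1.41) and Bub1 (-1.42). With the macrophage list as a covariate its adjusted p was 0.0597, in cKO replicate 5 against controls the median was 0.60, and with the skeletal muscle list as a covariate it was 0.50 (adjusted p = 0.195).

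Of the 13 mitochondrially encoded genes 3 fell, mt-Co2 (6.79-fold), mt-Co3 (5.55-fold) and mt-Atp6 (5.32-fold; by the ratio of means 3.97-fold, 3.58-fold and 3.55-fold; mt-Atp6 has no adjusted p in the authors' deposited table), with 4 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.602). These genes share 99.5%, 99.9% and 99.5% of their 100-base stretches with other annotated transcripts, and cKO replicate 5 (2044 for mt-Co2) lay at the level of the controls (2386 ± 371). Of 35 ribosomal protein genes 2 rose, including Rpl13 (3.63-fold, 18.4% shared; 4 when adjusted over the list alone; camera adjusted p = 0.602). Among 23 immediate early and dissociation-associated genes 5 rose, including Egr1 (3.07-fold), Dusp1 (2.43-fold), Jun (2.33-fold) and Jund (2.18-fold), and 2 fell, Fosl2 (1.55-fold) and Nr4a2 (2.29-fold; 15 and 4 when adjusted over the list alone). Camera adjusted p was 0.00252, and the adjusted p was 0.634 with an estimated correlation; the median was 1.12, and 0.34 in cKO replicate 5 against controls.

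The remaining signalling lists did not pass camera, while single members did. In the Wnt target list (19 members, camera adjusted p = 0.91) Lgr6 fell 2.71-fold and Lef1 3.27-fold, and Dkk1 rose (1 higher and 2 lower when adjusted over the list alone). Of 15 TGF-beta targets Pmepa1 (2.13-fold) and Col4a1 (2.78-fold) fell (3 when adjusted over the list alone; camera adjusted p = 0.221). Of 15 Notch genes Hes1 (2.64-fold) and Hey1 rose, and Nrarp (3.18-fold) and Maml2 (1.9-fold) fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.879, median -0.013, mean 0.022). Of 13 Hedgehog genes Gas1 rose 2.57-fold and the receptor gene Ptch1 fell 2.18-fold (2 and 3 when adjusted over the list alone; camera adjusted p = 0.876, median -0.034, mean 0.29). Of 18 angiogenic factors Slit3 (2.03-fold) and Serpinf1 rose, and Vegfa (2.19-fold) and Thbs1 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.716). Of 12 regulators of osteoclasts 1 passed, Il6 (1 when adjusted over the list alone; camera adjusted p = 0.602), and none of 26 interferon response genes did (0 when adjusted over the list alone; camera adjusted p = 0.342, and 0.0192, lower, without control 2; Ifit2 0.94 and Irf9 0.51 as log2 fold changes). None of 4 Y-linked genes passed between genotypes (log2 fold change 1.80 for Uty and 1.74 for Eif2s3y; 0 when adjusted over the list alone); control replicates 1 and 3 and cKO replicate 2 expressed Xist, with 870.1, 2192 and 2206 normalized counts, and the other 6 libraries had 0.

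In the authors' deposited table, 1657 genes were higher and 1051 lower in the knockout at an adjusted p under 0.05. Over the 14658 genes found in both, their log2 fold changes and those of limma had a Spearman correlation across genes of 0.935, genes not being independent replicates, and 95% had the same sign as in the authors' deposited table. Of 1132 limma calls among these genes, 1100 were also among the 2554 of the authors' deposited table. Grem1 had a log2 fold change of -2.67 in the authors' deposited table, with an adjusted p of 5.8e-09.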

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

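The tests of dilution and of a batch for the cartilage genes, thinning and the comparison at like depth were chosen after the result was seen, the depth class was defined from the data, and the single genes with copies were picked after their values were seen. A library was singled out where its gap to the nearest library of its group, divided by the range of the group, exceeded Dixon's 95% value. It occurred in 44 of the 298 groups of values examined. For independent, normally distributed values chance does so in about 5% of groups. Gene values here were normalized counts, where reads in 1 library and 0 in the others always give a ratio of 1. The 5% is therefore not the rate to compare with.

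Most of these cases set cKO replicate 5 apart from the other 4 cKO libraries, and this was also the knockout library of lowest depth (ratio 0.75; 43.5 against 76.3 to 87.2 M reads). Ratios, with the normalized count of replicate 5 against the range of the other 4, were as follows for matrix and cartilage genes: Col2a1 (0.851, 770230.1 against 22618 to 133768), Ucma (0.877, 3520.0 against 81.4 to 503), Hapln1 (0.859, 20322 against 676 to 3451), Col12a1 (0.893, 50853 against 7871 to 12451), Bgn (0.941, 137097 against 55243 to 60069), Itih5l-ps (0.912, 2392 against 2.17 to 213). For metabolic and mitochondrial genes they were Pfkl (0.815, 7172 against 2962 to 3739), Pgam1 (0.959, 2388 against 511 to 589), Eno1 (0.893, 21539 against 7172 to 8709.7), Pkm (0.845, 59792 against 36146 to 39821), Vegfa (0.757, 4395 against 1818 to 2444), Ndufa2 (0.741, 5886 against 8129 to 8911), Sdhc (0.859, 5752 against 7809 to 8145), mt-Atp6 (0.934, 2524 against 286 to 433), mt-Co3 (0.906, 4471 against 477 to 851), mt-Co2 (0.867, 2044 against 167 to 417), Rpl13 (0.713, 299 against 1117 to 1446). For further genes they were Malat1 (0.84, 86387 against 196184 to 217057), Kif20a (0.86, 2395 against 511 to 774), Mcam (0.729, 4997 against 2358 to 3074), Kit (0.852, 1571 against 717 to 844), Hba-a2 (0.945, 8891 against 37.3 to 521), Pf4 (0.807, 76.7 against 0 to 14.8), Nos2 (1, 426 against 0 to 0), Gcnt4 (0.976, 193 against 0 to 4.71). The mean log2 level of replicate 5 was apart for the fibrosis and matrix list (0.894; 15.4 against 14 to 14.2) and the LEPR niche list (0.773; 11.4 against 12.7 to 13.1).

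Other knockout libraries stood apart in single genes. In cKO replicate 1, Bcl6b (1; 105) and F8 (1; 88.3) had reads where the other 4 had 0. Replicate 2 was apart in Ltf (0.903, 59829 against 3559 to 9041), Ngp (0.875, 160997 against 5853 to 25262), Lck (0.935, 293 against 2.71 to 21.7) and Uty (0.75, 0 against 1121 to 1494). Among controls, replicate 2 alone or nearly alone held the reads of 5 muscle genes: Myot (1; 121 against 0), Myoz1 (0.947; 52.4 against 0 to 2.79), Myh4 (1; 1.38), Myh2 (1; 4.14) and Cox6a2 (1; 27.6). Control 4 held the reads of Tnnc1 (1; 2.79). Control 3 was apart in Ndufb8 (0.91; 7479 against 6252 to 6362) and Hba-a2 (0.859; 14648 against 3083 to 4712), and control 1 in Calcr (0.991; 327 against 0 to 2.79) and the mean of the osteoclast list (0.893; 11.1 against 8.89 to 9.12).

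Regrouping the 9 libraries argues against chance alone for the count of changed genes. Of 100 splits into 4 and 5 libraries, 2 gave 1184 genes or more, the real one included. The other was the split by read depth, cKO replicates 1 to 4 against the 4 controls with cKO replicate 5, which called 3686 genes, several times the real count, and points to a structure of the samples that follows depth more closely than genotype. The comparison at like depth called 83, but it has 1 knockout library, so its count cannot be set against those of the full groups.

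The first pattern weighed is the fall of cartilage genes, deep in cKO replicates 1 to 4 and slight in replicate 5. Read depth itself stays open: after all libraries were thinned to the smallest read total the list median was -4.15, against -4.13 before, but 1157 of the 1184 called genes kept their call, so thinning moved too little to test it. Dilution lowers every gene of the diluted cells alike, and the lower of the osteoblast and tendon list medians was 0.077. This argues against dilution only by RNA that lacks osteoblast and tendon genes, and only if those genes and the cartilage genes come from the same cells. Neither condition was tested, and the fibrosis and matrix list fell as well (median -1.28), so dilution by RNA of other cells is not excluded. A difference between library batches that goes with depth may account for the gap between replicate 5 and the other 4. The list mean of replicate 5 was -0.98 relative to the control mean and lay 0.156 above the lowest control. Members of the list had a median of -1.08 in replicate 5 against controls. Since control 3 had a lower list mean still (13.5, against 13.7 in replicate 5), this median does not decide about a batch. Replicate 5 is 1 library, and a genotype effect of different strength between animals, or tissue with less cartilage in 4 samples, stays open and untested.

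The second pattern concerns genes with near-identical copies. Comparing cKO replicates 1 to 4 with the other 5 libraries, 31% of 306 genes with at least 50% of their 100-base stretches in another gene passed limma's test, against 19.6% of single-copy genes of like mean, a ratio of 1.58 (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). The permutation shuffled genes, not libraries, and genes that share sequence do not vary independently, so its p understates the uncertainty. The idea came from mitochondrial and glycolytic genes already seen, which are among those counted. The neighbouring mitochondrial genes mt-Co2, mt-Atp6 and mt-Co3 were 9.63-fold, 7.71-fold and 8-fold lower in cKO replicates 1 to 4, while mt-Nd1 and mt-Nd2, with 0% and 3.19% shared, were 1.49-fold and 1.72-fold higher, but so was mt-Nd4 (1.33-fold), with 60.8% shared. In cKO replicate 5 against controls, copy genes shifted by a median of 0.291 log2 units and single-copy genes by 0.372, against 0.663 and 0.464 for the depth classes. Reads shared between copies may have been sequenced, aligned or counted differently in cKO replicates 1 to 4. This could bear on the calls for Eno1, Pgam1, Rpl13 and the 3 mitochondrial genes. However, glycolysis and hypoxia genes with 0% shared also fell in these libraries, Pfkl 3.68-fold and Vegfa 2.53-fold. Eno1 fell 3.32-fold and Pgam1 5.52-fold, so shared sequence need not account for their fall. Between genotypes, 25 of the 306 copy genes were called, against 1184 of all 15832 genes tested. The gene mt-Atp8, with 0% shared by this measure and 4.24-fold lower, and mt-Nd4 show that the measure misses some copies or that another cause acts.

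The third pattern is the rise of muscle genes in 5 of 5 cKO libraries. Immature muscle with embryonic myosins is argued against, since adult fast myosins (Myh1, Myh2 and Myh4) exceeded embryonic and neonatal ones (Myh3 and Myh8) by at least 14.46 times in every cKO library, but this does not cover muscle stem cells, whose genes were higher in a list chosen after the result was seen (7 of 12, median 3.28, Myf5 44.3 ± 43.6 in controls and 5149 ± 4032 in cKO libraries). RNA of muscle fibres in the sorted fraction is a candidate explanation: Acta1 reached a mean of 157077 normalized counts, and 16 of 20 genes of a second fibre list passed as higher, but without Tnnc1 and Cox6a2, already seen among the 10 largest increases, 14 of 18 did (77.8%), under the 80% set beforehand, so the test left it undecided; Des of the first list is also in the smooth muscle list. The sort for tdTomato should remove fibres that never expressed Lepr, though not their free RNA. Muscle stem cells as the sole source are less in keeping with cKO replicates 3 and 4, with Pax7 at 1928 and 566 but Acta1 at 32439 and 351238. The fibre and stem cell list means ran in opposite order over cKO replicates 1 to 4, but replicate 5 was lowest in both (11.5 and 11.3). These libraries are too few to exclude stem cells as the sole source. Whether tissue dissection, the sort or the genotype brought the RNA stays open, as the muscle signal and the genotype go together in all 9 libraries.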

How the results depend on the processing

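The muscle covariate, the depth class covariate, the comparison within libraries under 60 M reads, the joint exclusion of control replicates 1 and 3, and thinning were chosen after seeing the data; the others were planned. Grem1 was lower under all 27 alternatives (log2 fold change -4.34 to -2.36, adjusted p 3.0e-08 to 1) and past 0.05 in 23; it was not past it with the muscle covariate -4.34 (1), the depth class covariate -3.16 (0.143), under 60 M reads -3.16 (0.153) and without controls 1 and 3 -2.36 (0.0934), given as log2 fold change with adjusted p. As no control is deep, the depth class covariate and the libraries under 60 M reads give 1 and the same estimate, that of cKO replicate 5 against the controls, and differ in its spread alone. The replicate block likewise gives the estimate obtained without cKO replicate 5, whose number has no control. The 1184 changed genes became 786 with edgeR, 2546 with DESeq2, 4056 with library quality weights, 2715 with a replicate block (3562 without cKO replicate 5 and with no block), 95 with the macrophage covariate, 78 with the depth class covariate, 83 under 60 M reads, 338 without controls 1 and 3, and 377 to 3562 when 1 library was left out. With the muscle covariate limma called 0 (431 at an unadjusted p under 0.05), since that list nearly coincides with genotype. The share of higher calls was 61.7%, 60.6% with TMM and 65.6% with upper-quartile scaling, 21.8% with the depth class covariate, 78.3% under 60 M reads, 82.8% without controls 1 and 3, and 74.9% without control 1. Unless the construction is named, the cause was not tested. The replicate numbers showed no sign of pairing the libraries. Deviations of same-numbered libraries correlated at 0.0705, 0.0171, -0.00621 and -0.0109 for numbers 1 to 4. Of the 4 controls, 0 correlated best with its own number. So few libraries do not exclude a pairing. Gene list calls numbered 16, and 5 with the muscle covariate (2 of the 16 among them), 12 with the macrophage covariate (7 of the 16 lost beside the macrophage list itself), 8 with the depth class covariate, 8 under 60 M reads (1 knockout library), 0 with an estimated correlation, 4 with fry's directional and 28 with its mixed test; leaving out 1 library gave 13 to 18. Cell type lists past the exact test of means were 0, and 3 with medians; with 15 lists at least 3 must reach the smallest exact p to pass, and 6 or 9 when a control or a cKO library is left out, so exclusions of single libraries are not counted for this test. The Spearman correlation with the authors' deposited table was 0.949 at a mean of at least 50.

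With the muscle covariate, whose adjusted p was 1 for each of these genes, the log2 fold change turned for Myot -1.79, Mb -6.18, Cox6a2 -0.82, Nos2 1.51, Ihh 0.27, Itih5l-ps 2.42, Malat1 -0.57, Serpinf1 -0.29, Bgn 0.068, Rgmb -0.047, Fst -0.19, Dkk1 -0.85, Hes1 -0.32, Nrarp 1.25, Nr4a2 0.019, Ndufv1 -0.10, Ndufa2 -0.27, Slit3 -0.64, Vegfa 0.61, mt-Atp6 0.52, mt-Co3 0.55, mt-Co2 0.89, Sox10 -0.18, Prx -2.44, Perp -0.69, Ackr3 -0.40. Lists that turned with it in camera direction, with a call in the main test or with the covariate, had these medians: BMP targets -0.32, BMP ligands and receptors -0.26, LEPR niche -0.86, fibrosis and matrix 0.36, tendon -1.05, cell cycle 0.50, oxidative phosphorylation -0.17, erythroid 0.39, Schwann -0.42, mast cell 0.40. The epithelial median also changed sign, to -0.69, without such a turn. In cKO replicate 5 against controls, the estimate of both depth alternatives, these turned in camera direction in either of them: BMP targets -0.23, LEPR niche -0.44, fibrosis and matrix 0.11, cell cycle 0.60, erythroid 1.05, epithelial 0.012. The epithelial median kept its sign there (2.33 in the main test), and the megakaryocyte median changed sign to 0.27 without such a turn. With the macrophage covariate these turned in camera direction: neutrophil 1.40, B and plasma cell 1.88. The macrophage list itself turned too (0.034), but its mean is the covariate, so its mean change is 0 by construction. Of the called genes named here, 1 lost their call with TMM, 28 with edgeR, 5 with DESeq2 and 87 under 60 M reads, with no change of sign; 33 to 56 did when 1 control or 1 of cKO replicates 1 to 4 was left out, and 0 without cKO replicate 5. At this depth and replication simulated 2-fold changes were recovered in 18.9% of cases, so a gene without a call is not shown to be unaltered.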

Other observations

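The lists and tests in this part were chosen after the main results were seen; the 2 tests of the Pi16-type pattern were written down before their list had been measured, but the bounds of the second were set after an earlier value of it had been seen. Genes of muscle stem cells were higher in cKO libraries: 7 of 12 passed (median 3.28; camera p = 1.0e-05, and p = 0.132 with an estimated correlation). Pax7, the satellite cell regulator, had 82 to 1928 normalized counts in cKO libraries and 2.76 to 16.2 in controls. Of 12 genes of Col15a1-type fibroblasts, 5 rose and 1 fell, while Col15a1 itself was lower (12563 ± 4739.9 in controls and 6778 ± 2224 in cKO libraries, limma adjusted p = 0.108) without passing the test (list median 1.04; camera p = 0.00101, and p = 0.0739 with an estimated correlation). For the further muscle fibre genes the median was 6.28 (camera p = 3.4e-16, and p = 0.0251 with an estimated correlation).

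Pi16, Dpp4 and Clec3b rose and were above every control in 5 of 5 cKO libraries, and a larger share of Pi16-type fibroblasts among the sorted cells is a hypothesis for it. A further list of 12 such genes had a median of 0.79 (camera p = 0.000293), with 4 past the test as higher and none as lower; with an estimated correlation its p was 0.131. Connective tissue carried along with muscle could give the same rise. The cKO library with the least muscle RNA, replicate 5, had the lowest mean of the further list, at -0.82 log2 units relative to the mean of the other 4, and no rank differed by more than 1 between the 2 lists. Of the 120 orders of 5 libraries 8 are as close (6.67%), a count chosen after the ranks were seen, so too few libraries leave this explanation open. Replicate 5 is also the cKO library of lowest read depth.

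Control replicate 3 expressed Xist (2192) together with low levels of the Y-linked genes Ddx3y (109.8), Uty (39.8), Kdm5d (10.8) and Eif2s3y (4.31), where the 6 libraries without Xist had 3673 to 5591 for Ddx3y. Control 1, also with Xist, had 45.9 for Eif2s3y and 0 for the other 3.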
